A study of Homo sapiens with 34 samples.

How the data were processed

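Total RNA of 3 hepatocellular carcinoma lines was measured on Illumina arrays. Per the labels' protocols, the lines came from ATCC, RNA was taken up in Trizol, cleaned on RNeasy columns with DNase I and checked on a Bioanalyser, and biotinylated cRNA was made with the Ambion MessageAmp kit. Each of 17 groups, a line on a day, holds 2 arrays. The labels do not say whether the 2 arrays of a group come from separate cultures. The number of arrays limits the precision.

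The values used are linear probe intensities as deposited, 47230 probes on 34 arrays, positive throughout. How the authors normalized these intensities, and with which software, is not given in the sources used here. The percentiles of the deposited arrays coincide within each of 3 sets and differ between them. The first set holds the 12 arrays of HepG2 and of untreated SNU398 (medians from 182.91 to 183), the second the 12 arrays of treated SNU398 and of SNU475 untreated and at day 3 (172.65 to 172.73), and the third the 10 arrays of SNU475 from day 10 to day 56 (156.27 to 156.33). No group lies in more than 1 set, so the set could not be fitted as a block. SNU398 on every day, and SNU475 from day 10 on, are compared with untreated arrays of another set, and each such comparison carries any difference between sets that normalization did not remove. A deposited table of signals before normalization names its 72 columns by array barcode. No label ties a barcode to a sample, so these columns were not used here.

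Comparisons, lists, the rule for naming genes and most alternatives were chosen before the data were examined. The plan had been to correct background with negative control probes and to filter on detection p-values, which exist in the unmatched columns alone. Both steps were replaced after the unit of the deposited values was seen. Background was corrected with limma's normal-exponential model with an offset of 50 and the 34 arrays were quantile normalized together, on the log2 scale. A probe counted as above background in a group where both arrays exceeded 6.974, the mode of the mean sorted array (6.484) plus 1.645 times the spread below the mode (0.2981). Probes above background in at least 1 group were kept.

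Gene names came from the probe annotation, updated through Entrez identifiers with the RefSeq gene table of assembly GRCh38.p14, from which no positions were used. Of the probes, 30113 have 1 gene symbol, 8 have several and 17109 list none, and 30074 of those with 1 symbol matched the RefSeq table. After the filter 29365 probes stayed, 20999 with 1 symbol and 8361 with none listed. Probes with several symbols or none were not tested. Each gene was represented by its kept probe with the highest mean over the 34 arrays, which gave 15298 genes out of 20047 on the chip, 4335 of them with more than 1 kept probe. Y-linked genes and XIST, 41 of those tested, were not named. Among the increases and decreases named first on single days, 18 had another kept probe to set beside them, and in 3 it went the other way. Members of lists were not compared probe by probe. Replicate arrays correlated across kept genes with Pearson's r from 0.9915 to 0.9951 (genes are not independent replicates).

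One linear model with a mean for each of the 17 groups was fitted in limma 3.58.1 under R 4.3.3, with 17 residual degrees of freedom and 10.9 from the prior. Each treated day was compared with untreated cells of its line, day 3 with day 24 in each line and with day 56 in SNU475, and the mean effect over days 3, 10, 17 and 24 between each pair of lines, 21 comparisons in all. P-values are two-sided from limma's moderated test, adjusted by Benjamini-Hochberg within each comparison, and a gene was called at an adjusted p under 0.05. Where 1 of the groups was not above background, the fold change is printed as a bound, "at least N-fold", from the mean of the brighter group against the higher of the background threshold and the dimmer group's own mean. Differences between lines are bounded in the same way, and no size is given where the bound cannot be computed. Genes shared by lines were set beside the number that independent lines would share. Overlaps between days of a line were set beside n1 times n2 over N and beside 20 simulations without effects against shared untreated arrays.

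The 22 gene lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, each adjusted over the 462 tests of lists and comparisons. A list's call holds with the estimated correlation unless another value is printed for it. Medians and means of a list are over its measured members, log2 fold changes as fitted. Lists were matched by symbol and then by older name. MBD3 of the list of DNA methylation machinery had first been matched through an older name to DPEP3, and this was corrected after values had been seen, which left 15 measured members.

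Genes were named by a fixed rule. For each line at days 3, 10 and 24, and at day 56 in SNU475, these were the 5 largest increases and the 3 largest decreases among called genes with both treated arrays on the same side of both untreated arrays. For each list discussed they were up to 4 called members with the largest changes or, with none called, the 2 with the smallest p. DNMT1, DNMT3A, DNMT3B, UHRF1 and CDKN1A were followed on all days and AFP, ALB, CDH1 and VIM in untreated cells. Among genes raised or lowered in all 3 lines the 5 with the largest smallest change were named, and for each pair of lines the 3 largest fitted differences each way. The text leaves out some genes that the rule allows.

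The fit was tested on simulated data with changes of 1.5, 2 and 4-fold in 3 comparisons. It recovered 40.6, 36.4 and 40.8 percent of genes changed 1.5-fold in HepG2 at day 3, SNU398 at day 10 and SNU475 at day 3, then 70.1, 71.2 and 82.8 percent at 2-fold and 92.6, 92.6 and 95.5 percent at 4-fold. False calls were 16 of 152, 11 of 147 and 6 of 148. Estimated folds were compressed, 4-fold changes coming out at a median of 3.27, 3.02 and 3.42. In the list test a shift of 0.5 in the interferon list was called.

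Alternatives fixed at the start were median scaling, deposited values, no background correction, no filter, above background on all 34 arrays, the mean of a gene's probes, a trended robust prior, the compared lines alone, the replicate number as a block and leaving out each array. A block for the slide was not run, since barcodes are unmatched. References within a set (day 10 for SNU475, day 3 for SNU398) and a comparison of HepG2 and SNU475 at day 3 alone were added after the sets had been seen. DNA methylation and nucleosome accessibility, which the series design also names, were not analysed here.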

Results

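The series holds 34 Illumina arrays of the hepatocellular carcinoma lines HepG2, SNU398 and SNU475, in 17 groups of 2 arrays, untreated or sampled on later days after 3 daily doses of 100 nM SGI-110, an inhibitor of DNA methyltransferases. Treated cells were sampled at days 3, 10, 17 and 24 in each line and also at days 31 and 56 in SNU475. The comparisons below ask which genes differ from untreated cells on each day, which still differ at the latest days, which are shared by the 3 lines and which differ between them. A value after a gene is its log2 fold change with the standard error of the fit, with n = 2 arrays in each group compared, and a level is a normalized log2 mean with its SD. The labels do not state that replicates are separate cultures, so every p-value measures the spread between these samples, which may be technical. Untreated arrays exist at the start alone, so time in culture and treatment move together in every comparison with untreated cells. Of each gene list discussed the number of measured members that rose, fell and did not pass is given, then the count adjusted over the list alone, and where no second count is given it was the same.

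Untreated HepG2 showed high levels of the hepatocyte products AFP (15.83±0.04) and ALB (15.74±0.07). AFP was not above background in SNU398 (6.55±0.31) and stood at 8.75±0.02 in SNU475, with ALB at 9.18±0.21 and 8.42±0.08. The epithelial cadherin CDH1 lay at 8.98±0.02 in HepG2, 8.44±0.01 in SNU398 and 9.08±0.11 in SNU475. VIM, a mesenchymal filament, was high in SNU398 (14.97±0.26) and SNU475 (15.08±0.10) and lower in HepG2 (9.57±0.01).

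**Figure D1:**
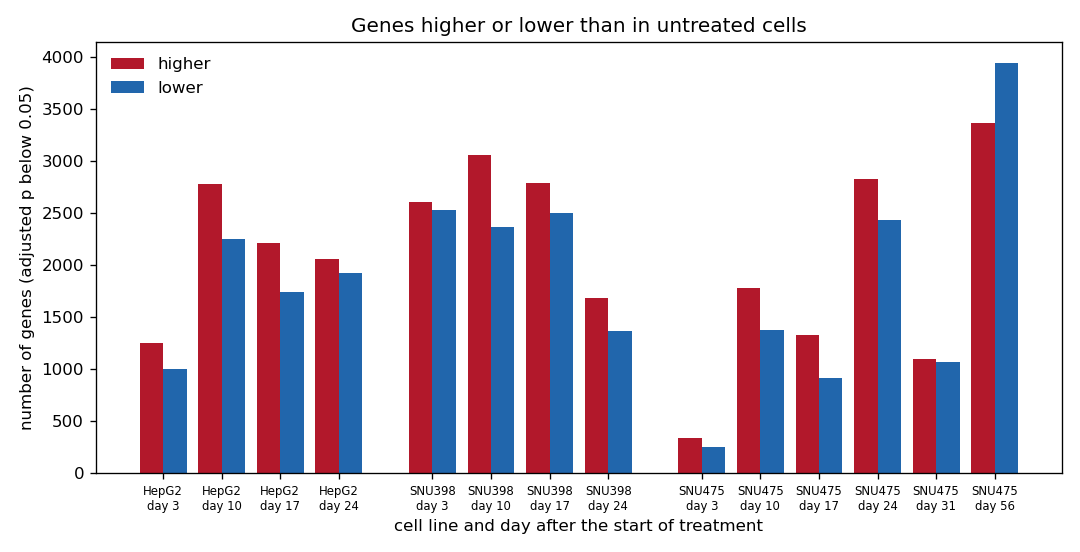
Genes higher or lower than in untreated cells in each line and on each day, out of 15298 tested. SNU475 went from 333 higher and 247 lower at day 3 to 3359 and 3939 at day 56.

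In HepG2 at day 3 the imprinted non-coding RNA H19 went from 6.42±0.36, not above background, to 11.83±0.05, at least 28.9-fold (adjusted p = 1.2e-21). MEG3, another imprinted non-coding RNA, rose by 3.82±0.17, 14.1-fold, with 1.53 on a second MEG3 probe, LRCH4 by 4.02±0.13, 16.3-fold, AGRP by 2.97±0.15 and WDR72 at least 5.6-fold. A second probe of LRCH4 read -0.21. LCN15 fell by 2.44±0.20, the glucose transporter SLC2A3 fell by 2.24±0.13 (adjusted p = 5.4e-13) and CHST15 fell by 2.21±0.12. In limma, 1248 genes were higher and 1000 lower at day 3, of which 209 and 61 changed at least 2-fold. Without untreated replicate 1 the total of 2248 dropped to 1480.

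Imprinted and oncofetal genes in HepG2 at day 3 included the further increases NNAT (2.85±0.14) and NDN (at least 3.83-fold), and of 23 measured, 5 rose, 2 fell and 16 did not pass (5 and 4 adjusted over the list alone). The list had a median of -0.06 against a mean of 0.49, and its test pointed up (adjusted p = 0.0982). Metallothionein genes rose, MT1H by 1.94±0.18, MT1M by 1.79±0.18, MT1X by 1.08±0.17 and MT1F by 1.03±0.14. In that list 8 of 9 rose and 1 did not pass (median 0.76, adjusted p = 2.77e-09). Cholesterol synthesis genes rose too, 11 of 16 with 5 not passing (12 and 0 adjusted over the list alone), with MVD at 0.92±0.13, LSS at 0.84±0.14 and HMGCS1 at 0.77±0.12 (list median 0.59, adjusted p = 5.39e-09). Genes of the hypoxia response fell, 14 of 21 with 7 not passing (0 and 17 adjusted over the list alone), among them the kinase gene HK2 (-1.45±0.14), LOX (-1.44±0.16), NDRG1 (-1.40±0.13) and PFKFB3 (-1.14±0.15), with a list median of -0.54 and adjusted p = 9.13e-11. Of 19 ATF4 and ER stress genes 2 rose, 9 fell and 8 did not pass (2 and 11 adjusted over the list alone), with ASNS at -0.90±0.12 and PSAT1 at -0.57±0.12 (median -0.31, adjusted p = 0.000768).

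Hepatocyte genes of HepG2 at day 3 numbered 9 higher, 1 lower and 32 not passing (10 and 1 adjusted over the list alone), with CYP3A5 at 1.24±0.15, VTN at 1.14±0.16 and APOC3 at 0.75±0.16 (median 0.17, adjusted p = 0.00709, and 0.0549 without day 3 replicate 2). Among 12 polyadenylated histone genes 6 rose, 1 fell and 5 did not pass (7 and 1 adjusted over the list alone), with H2BC12 at 1.09±0.14 and H3C4 at 0.76±0.15 (median 0.41, adjusted p = 0.00126, adjusted p = 0.0741 with an estimated correlation). Germline genes had 5 higher and 42 not passing, with PAGE1 at least 2.17-fold and PRAME at least 1.83-fold higher (median 0.07, adjusted p = 0.192). Of 20 epithelial genes 3 rose, 2 fell and 15 did not pass (4 and 3 adjusted over the list alone), SPINT2 at least 5.14-fold and CLDN7 at least 2.4-fold up. Their median of -0.05 differed in sign from the mean of 0.19 and the test. Markers of blood cells also moved in HepG2: FCER1G rose by 2.66±0.19, CD14 by 2.39±0.14 and CD68 by 0.81±0.12, while CD2 fell by 0.81±0.22. Of 15 such markers 4 rose, 2 fell and 9 did not pass, with a median of -0.02, a mean of 0.29 and a test pointing up (adjusted p = 0.236). DNMT1 stood at 0.10±0.13, DNMT3B at 0.26±0.12, UHRF1 at -0.15±0.14 and the cell cycle inhibitor CDKN1A at 0.07±0.14, none of which passed, and DNMT3A rose by 0.86±0.15.

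By day 10 H19 in HepG2 reached 14.17±0.01, at least 147-fold above untreated, and MEG3 rose by 5.50±0.17, 45.2-fold, with 2.89 on its second probe. Germline genes of the X chromosome followed, VCX at least 23.4-fold, GAGE12C at least 26.1-fold and VCX3B at least 25-fold. Probes of the PAGE, VCX, GAGE, MAGE, metallothionein and histone families may bind near-identical transcripts, so members of a family are not separate observations. LCN15 dropped by 4.99±0.20 and HAMP, the gene of the iron hormone hepcidin, dropped by 3.49±0.21, and SLC2A3 fell by 3.14±0.13. At this day 2772 genes were higher and 2246 lower, 531 and 419 of them at least 2-fold.

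Mitosis and proliferation genes, 36 of 36, fell in HepG2 at day 10, with BIRC5 at -3.07±0.13, BUB1 at -2.86±0.12, CDC20 at -2.82±0.15 and CCNB2 at -2.72±0.12 (list median -2.31, adjusted p = 4.65e-55). DNA replication genes fell in 30 of 31 cases with 1 not passing, such as CDC45 (-2.46±0.12), TK1 (-2.41±0.12) and MCM10 (-2.33±0.14), for a median of -1.48 (adjusted p = 7.04e-33). Polyadenylated histone genes went the other way, 10 of 12 higher and 2 not passing, with H2BC21 at 2.34±0.13, H4C8 at 2.34±0.16 and H2AC18 at 2.26±0.15 (median 1.88, adjusted p = 6.61e-11). UHRF1, which brings DNMT1 to replicating DNA, fell by 2.40±0.14, HELLS fell by 1.82±0.13, DNMT1 by 0.59±0.13 and DNMT3B by 0.71±0.12, whereas MBD4 rose by 0.85±0.13. The DNA methylation machinery list held 5 higher, 7 lower and 3 not passing (6 and 7 adjusted over the list alone), and its median of 0.25 differed in sign from its mean of -0.20 and its test (adjusted p = 0.505). CDKN1A rose by 0.70±0.14, and of 31 p53 targets 14 rose, 3 fell and 14 did not pass, including ZMAT3 (1.31±0.15), GDF15 (0.83±0.16) and SESN2 (0.79±0.13), with a median of 0.20 (adjusted p = 0.0395, 0.0534 above background on all 34 arrays, 0.0542 without untreated replicate 2 and 0.0703 without day 10 replicate 1).

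Germline and cancer-testis genes in HepG2 at day 10 had 24 higher, 3 lower and 20 not passing (24 and 4 adjusted over the list alone). PAGE1 was at least 11.4-fold, PAGE5 at least 6.77-fold and PAGE2 at least 6.08-fold higher, and TKTL1 rose by 2.55±0.16 (list median 0.41, adjusted p = 2.25e-06). The hepatocyte list had 22 higher, 3 lower and 17 not passing (24 and 3 adjusted over the list alone), with VTN at 3.07±0.16, G6PC1 at 2.78±0.22 and CYP3A5 at 2.36±0.15 (median 0.50, adjusted p = 2.85e-06, 0.825 above background on all 34 arrays). Among epithelial genes 10 rose, 3 fell and 7 did not pass, SPINT2 being at least 12.2-fold and CLDN7 at least 4.16-fold higher and CDH1 up by 1.96±0.15 (median 0.36, adjusted p = 0.00148). Genes reported as hypermethylated in liver cancer numbered 12 higher, 4 lower and 17 not passing, with UCHL1 at least 3.17-fold up and DLC1 up by 1.90±0.11 (median 0.18, adjusted p = 0.00925, 0.17 above background on all 34 arrays). HLA-B, a class I antigen gene, rose by 2.85±0.14 and ERAP2 by 1.24±0.14, and the antigen presentation list counted 8 higher, 1 lower and 13 not passing (8 and 2 adjusted over the list alone, median 0.10, adjusted p = 0.106). Of 36 interferon response genes 7 rose, 7 fell and 22 did not pass (8 and 7 adjusted over the list alone), with IFI27 at 1.54±0.14, HERC5 at 1.24±0.16 and IFITM1 at -1.37±0.16. Their median of -0.06 and test pointed down against a mean of 0.00 (adjusted p = 0.75).

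Stress and metabolic lists of HepG2 at day 10 split. Of 19 ATF4 and ER stress genes 10 rose, 1 fell and 8 did not pass, with ATF3 up 2.82-fold, TRIB3 at 1.46±0.13 and DDIT3 at 1.21±0.13 (median 0.33, adjusted p = 0.000319). Cholesterol synthesis genes counted 1 higher, 10 lower and 5 not passing, FDPS at -0.92±0.13 and SQLE at -0.73±0.13 (median -0.47, adjusted p = 0.00689, adjusted p = 0.0949 with an estimated correlation). Metallothionein genes had 2 higher, 6 lower and 1 not passing, MT2A at -1.35±0.17 and MT1E at -1.26±0.15 (median -0.60, adjusted p = 0.0187, adjusted p = 0.203 with an estimated correlation, and 0.0745 on the mean of all probes and 0.0663 without day 10 replicate 1). Hypoxia genes stayed low, 3 higher, 15 lower and 3 not passing (3 and 16 adjusted over the list alone), with LOX at -3.08±0.16 and PFKFB4 at -2.21±0.14 (median -0.76, adjusted p = 8.23e-07). NF-kB and chemokine genes had 9 higher and 11 not passing (10 and 0 adjusted over the list alone), CXCL2 at 1.77±0.18 and CXCL8 at 1.47±0.17 (median 0.33, adjusted p = 0.00531, 0.0937 above background on all 34 arrays). CD14 rose by 3.76±0.14, FCER1G by 2.22±0.19 and the endothelial gene VWF by 1.80±0.19, while CD2 fell by 0.87±0.22. The blood cell list had 4 higher, 3 lower and 8 not passing, with a median of -0.16 against a mean of 0.40 and a test pointing up (adjusted p = 0.349).

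At day 17 in HepG2 2209 genes were higher and 1739 lower. H19 was at least 67.7-fold up, MEG3 up by 4.42±0.17 and the nucleoside transporter SLC29A2 by 2.63±0.16. Metallothionein genes rose again, 8 of 9 with 1 not passing, MT1B at least 7.3-fold and MT1H by 3.28±0.18 (median 1.53, adjusted p = 3.86e-12). Mitosis genes had 16 lower and 20 not passing (0 and 17 adjusted over the list alone), with NEK2 at -0.75±0.12 and CDK1 at -0.70±0.10 (median -0.28, adjusted p = 2.03e-06).

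At day 24 H19 in HepG2 was still at least 66.6-fold above untreated, MEG3 rose by 4.03±0.17 (1.86 on its second probe), WDR72 at least 10.7-fold, and the glutathione transferases GSTA1 and GSTA2 rose by 4.21±0.16, 18.6-fold, and 4.16±0.18, 17.9-fold. LCN15 fell by 3.12±0.20, SLC2A3 fell by 2.83±0.13 and the calcium channel gene ITPR3 by 2.42±0.12 (adjusted p = 4.3e-15). In all, 2052 genes were higher and 1922 lower, 405 and 185 at least 2-fold. Cholesterol synthesis genes rose in 15 of 16 cases with 1 not passing, HMGCS1 by 1.81±0.12, LSS by 1.68±0.14 and MVD 2.82-fold (median 1.12, adjusted p = 1.62e-16). Hepatocyte genes had 20 higher and 22 not passing (21 and 0 adjusted over the list alone), with ITIH1 at 2.32±0.20, HPX at 2.03±0.14 and APOC3 at 1.99±0.16 (median 0.39, adjusted p = 2.75e-09, 0.112 above background on all 34 arrays). Mitosis genes were again lower, 35 of 36 with 1 not passing, CEP55 at -1.25±0.15 and PLK1 at -1.16±0.14 (median -0.68, adjusted p = 2.14e-18), and so were 22 of 31 DNA replication genes with 9 not passing (0 and 25 adjusted over the list alone), GINS3 at -1.04±0.14 and CDC45 at -0.96±0.12 (median -0.60, adjusted p = 1.79e-11).

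Germline genes at day 24 in HepG2 had 15 higher, 2 lower and 30 not passing (16 and 2 adjusted over the list alone), PRAME at least 5.36-fold, PAGE5 at least 5.18-fold and PAGE1 at least 5.01-fold up (median 0.15, adjusted p = 0.000231). Imprinted and oncofetal genes had 8 higher, 2 lower and 13 not passing (8 and 3 adjusted over the list alone), NDN at least 3.16-fold and NNAT among the former (median 0.24, adjusted p = 0.000275, 0.319 above background on all 34 arrays). Metallothionein genes counted 6 higher and 3 not passing, MT1H at 1.97±0.18 and MT1M at 1.90±0.18 (median 0.65, adjusted p = 0.000106, 0.0779 above background on all 34 arrays). Hypoxia genes had 2 higher, 11 lower and 8 not passing (2 and 15 adjusted over the list alone), with the glucose transporter SLC2A1 at -1.98±0.14 and PFKFB3 at -1.75±0.15 (median -0.41, adjusted p = 6.03e-05). Histone genes had 8 higher and 4 not passing (8 and 1 adjusted over the list alone), H2BC12 at 1.19±0.14 and H2BC5 at 1.05±0.14 (median 0.61, adjusted p = 0.000638, adjusted p = 0.0601 with an estimated correlation). NF-kB genes had 4 higher and 16 not passing, CXCL2 at 1.99±0.18 and TNFAIP3 at 1.16±0.15 (median 0.14, adjusted p = 0.0177, adjusted p = 0.064 with an estimated correlation, 0.113 above background on all 34 arrays). Liver cancer hypermethylated genes numbered 10 higher, 4 lower and 19 not passing (13 and 5 adjusted over the list alone), GSTP1 at 1.16±0.13 and CDH1 at 1.10±0.15 (median 0.19, adjusted p = 0.0389, 0.182 above background on all 34 arrays, 0.0596 when HepG2 was fitted on its own, 0.112 without untreated replicate 2 and 0.0717 without day 24 replicate 1). The housekeeping list had 5 lower and 10 not passing, HPRT1 at -0.83±0.14 and GAPDH at -0.47±0.12 (median -0.16, adjusted p = 0.0406, adjusted p = 0.119 with an estimated correlation, 0.102 above background on all 34 arrays, 0.0513 when HepG2 was fitted on its own, 0.141 without untreated replicate 1 and 0.0627 without day 24 replicate 2). Nucleoside drug handling genes counted 2 higher, 7 lower and 8 not passing (2 and 9 adjusted over the list alone), SLC29A2 up by 2.54±0.16 and ADA at -1.33±0.13 (median -0.38, adjusted p = 0.122), and no day of any line gave a call for this list.

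In SNU398 at day 3 the NADPH oxidase subunit gene CYBA went from 6.92±0.06, not above background, to 11.24±0.01, at least 19.2-fold (adjusted p = 4.7e-20). CTCFL, a testis relative of CTCF, was at least 12.4-fold higher, PAGE2B at least 13.5-fold, CRIP1 at least 16.2-fold and MAP1LC3A at least 6.69-fold, with 0.19 on a second MAP1LC3A probe. The immediate early genes FOSB (-3.33±0.16) and JUN (-2.54±0.15) fell, and NBDY fell by 2.68±0.14 (adjusted p = 1.3e-14). Against untreated cells 2606 genes were higher and 2525 lower, 362 and 319 of them at least 2-fold. The treated SNU398 arrays belong to another array set than the untreated ones, and with median scaling 68.4 percent of the called genes were higher against 50.8 in the main analysis.

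Germline and cancer-testis genes rose in SNU398 at day 3, 30 of 47 with 17 not passing, among them GTSF1 (at least 4.04-fold), PAGE5 (at least 3.66-fold) and PAGE2 (at least 3.56-fold), a median of 0.64 and adjusted p = 1.45e-14. ATF4 and ER stress genes fell, 1 higher, 15 lower and 3 not passing (1 and 16 adjusted over the list alone), with TRIB3 at -2.51±0.13, DDIT3 at -2.40±0.13 and DDIT4 at -1.84±0.11 (median -0.93, adjusted p = 1.62e-12). DNA replication genes had 18 higher, 1 lower and 12 not passing (20 and 1 adjusted over the list alone), RRM2 rising by 1.97±0.18 and CCNE1 by 0.94±0.13 (median 0.41, adjusted p = 4.52e-05). Of 20 WNT antagonists and targets 6 rose and 14 did not pass, with the secreted antagonists DKK1 at 1.68±0.11 and SFRP1 at 1.40±0.15 (median 0.26, adjusted p = 0.00532). In the DNA methylation machinery 7 rose, 1 fell and 7 did not pass (8 and 1 adjusted over the list alone): HELLS by 1.28±0.13, DNMT3B by 0.85±0.12, UHRF1 by 0.63±0.14 and DNMT1 by 0.47±0.13 (median 0.38, adjusted p = 0.0124). CDKN1A rose by 0.62±0.14 and TP53I3 by 1.90±0.13, while DDB2 fell by 1.27±0.14, and p53 targets together had 5 higher, 7 lower and 19 not passing (5 and 8 adjusted over the list alone, median -0.06, adjusted p = 0.438).

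Some list calls of SNU398 at day 3 were lost with an estimated correlation or without 1 array. Antigen presentation had 1 higher, 7 lower and 14 not passing (1 and 10 adjusted over the list alone), HLA-DMB at -1.06±0.19 (median -0.22, adjusted p = 0.04, adjusted p = 0.22 with an estimated correlation, 0.0839 above background on all 34 arrays, 0.0805 without untreated replicate 1 and 0.134 without day 3 replicate 1). Cholesterol synthesis had 1 higher, 7 lower and 8 not passing, HMGCS1 at -0.94±0.12 (median -0.27, adjusted p = 0.0231, adjusted p = 0.165 with an estimated correlation and 0.086 without day 3 replicate 2). Metallothionein genes had 2 higher and 7 not passing, MT1E at 1.38±0.15 (median 0.32, adjusted p = 0.0416, adjusted p = 0.262 with an estimated correlation, 0.177 above background on all 34 arrays, 0.0972 with median scaling, 0.0947 on the deposited values, 0.124 on the mean of all probes, 0.0537 with SNU398 on its own, 0.0724 without untreated replicate 1 and 0.141 without day 3 replicate 2). NNAT was at least 9.1-fold and H19 at least 2.29-fold higher. CDH1 fell at least 2.76-fold to background.

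At day 10 PAGE2B in SNU398 reached 12.66±0.17, at least 51.4-fold above untreated (adjusted p = 9.6e-22), VCX3B rose by 6.21±0.15, 74-fold, VCX by 6.17±0.16, VCX3A by 5.81±0.17, with 2.46 on a second VCX3A probe, and the testis dipeptidase gene DPEP3 at least 25.8-fold. GSTO2 fell by 2.49±0.16, CLPSL2 fell by 2.34±0.14 and the meiotic gene MND1 by 2.33±0.15 (adjusted p = 3.4e-13). There were 3055 genes higher and 2358 lower, 584 and 318 at least 2-fold, and 72.3 percent were higher with median scaling against 56.4. Germline genes had 32 higher, 1 lower and 14 not passing (34 and 3 adjusted over the list alone), CTCFL at least 27.3-fold, MAEL at least 22.7-fold, PAGE2 at least 21.7-fold and PAGE5 at least 19.3-fold (median 1.27, adjusted p = 8.92e-21).

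Mitosis genes fell in SNU398 at day 10, 35 of 36 with 1 not passing: AURKB at -2.15±0.13, KIF20A at -2.13±0.12, TOP2A at -2.02±0.12 and CDK1 at -1.98±0.10 (median -1.41, adjusted p = 4.8e-36). Replication genes had 1 higher, 18 lower and 12 not passing (1 and 20 adjusted over the list alone), PRIM1 at -1.70±0.15 and TYMS at -1.26±0.12 (median -0.49, adjusted p = 1.44e-07). Interferon response genes rose, 18 with 3 lower and 15 not passing (19 and 3 adjusted over the list alone), IRF7 at least 5.02-fold, IFI27 by 2.35±0.14, IFITM3 by 2.31±0.14 and ISG15 by 2.18±0.12 (median 0.39, adjusted p = 2.93e-05). Antigen presentation followed with 9 higher, 2 lower and 11 not passing (12 and 2 adjusted over the list alone), HLA-DPA1 at least 2.9-fold and HLA-DMA by 1.63±0.12 (median 0.34, adjusted p = 0.00743, adjusted p = 0.113 with an estimated correlation). Mesenchymal genes had 18 higher, 1 lower and 11 not passing (18 and 3 adjusted over the list alone), TGFBI at least 7.44-fold, LOX at least 7.43-fold and CCN2 by 2.76±0.13 (median 0.50, adjusted p = 4.28e-05). WNT antagonists and targets had 14 higher and 6 not passing, DKK1 at 2.60±0.11 and SFRP1 at 1.71±0.15 (median 0.48, adjusted p = 0.000111). Liver cancer hypermethylated genes had 17 higher, 4 lower and 12 not passing (18 and 4 adjusted over the list alone), NQO1 at 3.61±0.13, GSTP1 at 2.26±0.13 and TFPI2 at least 3.22-fold (median 0.34, adjusted p = 0.00152, 0.0647 above background on all 34 arrays).

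ATF4 and ER stress genes of SNU398 were higher at day 10 after being lower at day 3, with 11 of 19 up and 8 not passing, DDIT4 at 2.12±0.11 and SESN2 at 1.39±0.13 (median 0.40, adjusted p = 0.000638). GDF15 rose by 2.61±0.16 and CDKN1A by 1.28±0.14, and p53 targets had 9 higher, 5 lower and 17 not passing (9 and 6 adjusted over the list alone, median 0.07, adjusted p = 0.291). Cholesterol synthesis genes had 1 higher, 11 lower and 4 not passing, MSMO1 at -1.72±0.12 and HMGCS1 at -1.52±0.12 (median -0.87, adjusted p = 2.68e-07). Of 12 histone genes 8 rose, 1 fell and 3 did not pass, H2AC18 by 2.18±0.15 and H2AC20 by 2.13±0.16 (median 0.91, adjusted p = 8.58e-05). DNMT1 (-0.07±0.13), DNMT3A (-0.10±0.15), DNMT3B (0.18±0.12) and UHRF1 (-0.03±0.14) did not pass.

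At day 17 in SNU398 2781 genes were higher and 2495 lower, 69.4 percent higher with median scaling against 52.7. CTCFL was at least 22.4-fold and GTSF1 at least 10.6-fold higher, in a germline list of 33 higher and 14 not passing (36 and 0 adjusted over the list alone, median 0.73, adjusted p = 1.35e-18). ATF4 genes were lower again, 2 higher, 13 lower and 4 not passing, TRIB3 at -2.17±0.13 and DDIT3 at -2.13±0.13 (median -0.80, adjusted p = 1.66e-08). The interferon list had 13 higher, 4 lower and 19 not passing, IFIT1 at 1.07±0.14 and ISG15 at 0.95±0.12 (median 0.25, adjusted p = 0.0159, 0.0717 with median scaling, 0.126 on the deposited values and 0.125 above background on all 34 arrays). Metallothionein genes had 6 higher and 3 not passing, MT1G at least 3.42-fold and MT2A by 1.40±0.17 (median 0.86, adjusted p = 0.000261, adjusted p = 0.0524 with an estimated correlation).

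At day 24 in SNU398 CTCFL was at least 22.6-fold above untreated, the lactate dehydrogenase gene LDHB at least 24.7-fold (6.60±0.15 to 11.60±0.25), CYBA at least 17.2-fold, GTSF1 at least 14.7-fold and CRIP1 at least 12.9-fold. ALKAL1 fell by 2.23±0.17, SNORA12 by 1.98±0.18 and FOSB fell by 1.67±0.16 (adjusted p = 9.5e-09). Here 1684 genes were higher and 1361 lower, 211 and 70 at least 2-fold, and 78.7 percent were higher with median scaling against 55.3. Without untreated replicate 2 the total of 3045 dropped to 1797. Germline genes had 27 higher and 20 not passing, MAEL at least 9.01-fold and PAGE5 at least 4.45-fold (median 0.60, adjusted p = 1.42e-15). WNT antagonists DKK1 (3.28±0.11) and SFRP1 (1.96±0.15) were higher in a list of 5 higher and 15 not passing (median 0.19, adjusted p = 0.00229). Interferon genes had 11 higher, 1 lower and 24 not passing (15 and 1 adjusted over the list alone), IRF7 at least 3.41-fold and ISG15 by 1.55±0.12 (median 0.15, adjusted p = 0.000207). Replication genes had 12 higher, 2 lower and 17 not passing (14 and 2 adjusted over the list alone), POLA1 at 0.83±0.13 and CDC45 at 0.69±0.12 (median 0.28, adjusted p = 0.0001), and in the DNA methylation machinery 5 rose and 10 did not pass, HELLS by 0.72±0.13 and DNMT1 by 0.59±0.13 (median 0.20, adjusted p = 0.0177). CDKN1A stayed higher by 0.96±0.14.

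In SNU475 at day 3 H19 rose by 4.01±0.14, 16.1-fold, from 8.23±0.05 to 12.24±0.15 (adjusted p = 4.2e-18). TYROBP, an adaptor gene of myeloid cells, was at least 4.11-fold higher, SOX15 rose by 2.32±0.17, PAGE2B by 2.32±0.17 and the germline gene FMR1NB at least 2.85-fold. HINT3 fell by 2.31±0.13, APP by 1.69±0.28 and the small nuclear RNA RNU11 fell by 1.32±0.16. Second probes read 0.24 for HINT3 and -1.71 and 0.20 for APP. In limma 333 genes were higher and 247 lower, 91 and 11 of them at least 2-fold, with 311 to 361 called when any 1 of the 4 arrays was left out. Requiring signal above background on all 34 arrays left 147 higher and 220 lower, 40.1 percent higher against 57.4.

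Germline genes in SNU475 at day 3 had 9 higher and 38 not passing (11 and 1 adjusted over the list alone), TKTL1 at 1.85±0.16, MAGEB2 at least 2.32-fold and MAGEA4 at least 2.04-fold (median 0.10, adjusted p = 2.94e-08). Epithelial genes had 5 higher and 15 not passing (8 and 1 adjusted over the list alone), SPINT2 at least 2.81-fold and KRT18 by 0.71±0.16 (median 0.31, adjusted p = 0.000372). IFI27 rose by 2.06±0.14 and IRF7 by 0.80±0.15 in an interferon list of 2 higher and 34 not passing (4 and 0 adjusted over the list alone, median 0.09, adjusted p = 0.0161). The blood and immune cell list had 1 higher, TYROBP, and 14 not passing (3 and 0 adjusted over the list alone, median 0.10, adjusted p = 0.0202). Calls lost with an estimated correlation were those of antigen presentation, 1 higher, HLA-G at 0.50±0.13, and 21 not passing (2 and 0 adjusted over the list alone, median 0.16, adjusted p = 0.0104, adjusted p = 0.128 with an estimated correlation), and metallothionein, 2 higher, MT1F at 1.19±0.14 and MT1E at 0.81±0.15, and 7 not passing (median 0.22, adjusted p = 0.00405, adjusted p = 0.12 with an estimated correlation). Histone genes had 3 lower and 9 not passing (0 and 4 adjusted over the list alone), H2AC20 at -0.86±0.16 (median -0.24, adjusted p = 0.000481, adjusted p = 0.0555 with an estimated correlation). Mitosis genes had 1 lower and 35 not passing (median -0.12, adjusted p = 0.0237, adjusted p = 0.156 with an estimated correlation, 0.0581 above background on all 34 arrays). Without untreated replicate 2 or day 3 replicate 1 the interferon (0.0711 and 0.0511), blood cell (0.052 and 0.0708) and mitosis calls (0.0539 and 0.101) were lost. The histone call was lost without day 3 replicate 2 (0.0555). Collagen and fibroblast genes rose singly, THY1 by 1.63±0.14, COL1A2 by 1.38±0.18 and COL1A1 by 1.23±0.12. The mesenchymal list had 5 higher, 1 lower and 24 not passing (5 and 2 adjusted over the list alone), with a median of -0.09 against a mean of 0.07 and a test pointing up (adjusted p = 0.575). DNMT1 (-0.24±0.13), DNMT3B (0.39±0.12), UHRF1 (0.10±0.14) and CDKN1A (0.22±0.14) did not pass, and DNMT3A was not above background.

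By day 10 in SNU475 H19 was up by 4.68±0.14, 25.6-fold, PAGE2B by 4.48±0.17, 22.3-fold, the HLA region RNA HCP5 by 3.96±0.13, S100P at least 10.2-fold and IFI27 by 3.84±0.14 (adjusted p = 6.2e-18). NR4A2 fell by 2.94±0.17, the endothelin gene EDN2 fell by 2.48±0.14 and SNAI2, a repressor of epithelial genes, by 2.35±0.20. From day 10 on the SNU475 arrays form another set than the untreated ones, and on the deposited values their all-gene median shifted by -0.20 to -0.24. There were 1775 genes higher and 1375 lower, 56.3 percent higher against 33.7 with median scaling and 12.2 on the deposited values, where the total was 6307. Without untreated replicate 1 the total was 2006.

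Antigen presentation rose in SNU475 at day 10, 17 of 22 with 5 not passing, HLA-B by 1.66±0.14, HLA-F by 1.28±0.14 and HLA-C by 1.24±0.14 (median 0.65, adjusted p = 7.31e-11). Interferon genes had 13 higher and 23 not passing (13 and 1 adjusted over the list alone), BST2 at 1.70±0.14 and IFITM1 at 1.63±0.16 (median 0.13, adjusted p = 0.00315). ATF4 and ER stress genes had 12 higher, 2 lower and 5 not passing (12 and 3 adjusted over the list alone), TRIB3 at 2.23±0.13, ASNS at 1.92±0.12 and PSAT1 at 1.88±0.12 (median 0.79, adjusted p = 3.67e-07). Mitosis genes fell, 36 of 36, KIF20A at -1.41±0.12, KIF11 at -1.37±0.15 and CENPF at -1.31±0.14 (median -0.98, adjusted p = 3.92e-37), as did 26 of 31 replication genes with 5 not passing, GINS2 at -1.57±0.13 and TYMS at -1.30±0.12 (median -0.65, adjusted p = 2.26e-19). Germline genes had 15 higher, 3 lower and 29 not passing, PAGE2 at least 7.61-fold, PAGE5 at least 6.22-fold and MAGEA4 at least 5.55-fold (median 0.14, adjusted p = 0.000311). Epithelial genes had 9 higher, 4 lower and 7 not passing, SPINT2 at least 5.67-fold and CDH1 by 1.53±0.15 (median 0.34, adjusted p = 0.0447, adjusted p = 0.0601 with an estimated correlation, 0.052 with SNU475 on its own, 0.0545 without day 10 replicate 2). UHRF1 fell by 0.77±0.14 and DNMT1 by 0.70±0.13, CDKN1A rose by 0.52±0.14 and GDF15 by 2.11±0.16, and p53 targets had 7 higher, 3 lower and 21 not passing (8 and 4 adjusted over the list alone, median 0.08, adjusted p = 0.297).

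At day 17 in SNU475 1326 genes were higher and 916 lower, 59.1 percent higher against 34.5 with median scaling and 10.4 on the deposited values, with a total of 5833 on those. Without any 1 of the 4 arrays the total was 1318 to 1444. IFI27 (3.93±0.14) and BST2 (1.97±0.14) stayed up in an interferon list of 12 higher and 24 not passing (median 0.21, adjusted p = 3.31e-05). HLA-B rose by 1.46±0.14, with 12 antigen presentation genes higher and 10 not passing (16 and 0 adjusted over the list alone, median 0.58, adjusted p = 5.77e-11).

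At day 24 in SNU475 PAGE2B rose by 4.65±0.17, 25.1-fold, PAGE2 at least 11.1-fold, IFI27 16-fold, H19 by 3.79±0.14 and the lipoprotein gene APOE by 3.73±0.12 (adjusted p = 1.4e-18). FOSB fell by 3.30±0.16, ABL2 fell by 3.26±0.16, with -3.91 and -0.62 on 2 other ABL2 probes, and EDN2 at least 8.7-fold. Of the genes tested 2828 were higher and 2426 lower, 454 and 294 at least 2-fold, 53.8 percent higher against 38.8 with median scaling and 18.8 on the deposited values. Antigen presentation genes had 18 higher, 1 lower and 3 not passing, HLA-B at 1.97±0.14, HLA-F at 1.74±0.14 and HLA-DMB at 1.42±0.19 (median 0.93, adjusted p = 3.2e-09). Interferon genes had 14 higher, 3 lower and 19 not passing (15 and 4 adjusted over the list alone), IFITM1 at 1.89±0.16 and ISG20 at 1.56±0.17 (median 0.22, adjusted p = 0.0159, 0.0503 above background on all 34 arrays). ATF4 genes had 14 higher, 3 lower and 2 not passing, TRIB3 at 2.27±0.13 and ASNS at 1.97±0.12 against ATF3 at -2.40±0.13 (median 0.81, adjusted p = 2.46e-06). Mitosis genes had 32 lower and 4 not passing (0 and 33 adjusted over the list alone), KIF11 at -1.44±0.15 and CEP55 at -1.40±0.15 (median -0.77, adjusted p = 1.02e-16), and replication genes 26 lower and 5 not passing, RRM2 at -2.02±0.18 (median -0.69, adjusted p = 5.3e-15). Germline genes had 15 higher, 9 lower and 23 not passing (16 and 10 adjusted over the list alone, median 0.10, adjusted p = 0.0743). UHRF1 fell by 1.12±0.14.

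At day 31 in SNU475 1090 genes were higher and 1070 lower, 50.5 percent higher against 27.3 with median scaling and 7.57 on the deposited values, with a total of 5930 on those. Without any 1 of the 4 arrays it was 1242 to 1421. Mitosis genes had 6 higher and 30 not passing, CDK1 up by 0.63±0.10 and MKI67 by 0.60±0.16 (median 0.20, adjusted p = 0.000471). Germline genes held 15 higher, 2 lower and 30 not passing, PAGE2 at least 9.49-fold and PAGE5 at least 9.4-fold (median 0.19, adjusted p = 1.89e-05), IFI27 was up by 3.35±0.14 and H19 by 2.56±0.14. Metallothionein genes had 5 higher and 4 not passing, MT1F at 0.72±0.14 (median 0.56, adjusted p = 0.0222, adjusted p = 0.216 with an estimated correlation, 0.0715 without untreated replicate 1). Cholesterol genes had 7 lower and 9 not passing, HSD17B7 at -1.20±0.12 (median -0.24, adjusted p = 0.00121, adjusted p = 0.052 with an estimated correlation).

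At day 56 in SNU475 CEMIP, a hyaluronan-degrading gene, went from 6.51±0.05 to 13.17±0.10, at least 73.2-fold (adjusted p = 5e-26). IFITM1 rose by 5.95±0.16, 61.7-fold, the collagen gene COL6A3 by 5.79±0.16, 55.5-fold, THY1 by 5.49±0.14, 45-fold, and MME by 5.47±0.17. TM4SF4 fell at least 32.4-fold, SLC27A2 fell by 3.85±0.12 and AGR2 fell by 4.23±0.15, with -0.42 on a second AGR2 probe. Here 3359 genes were higher and 3939 lower, 1101 and 836 at least 2-fold, 46 percent higher against 23.1 on the deposited values.

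Mesenchymal genes in SNU475 at day 56 had 19 higher, 5 lower and 6 not passing, LOX at 4.47±0.16, CDH11 at least 13.2-fold and COL1A2 at 3.73±0.18 (median 0.69, adjusted p = 3.04e-06, but median -0.16 and 0.611 above background on all 34 arrays). The epithelial list had 3 higher, 10 lower and 7 not passing, KRT8 at -2.99±0.15, CLDN7 at -2.92±0.15 and ELF3 at -2.67±0.12 (median -0.56, adjusted p = 0.00743). Cholesterol synthesis genes had 13 higher, 1 lower and 2 not passing, HMGCS1 at 2.40±0.12 and SC5D at 1.95±0.15 (median 0.76, adjusted p = 4.28e-05). Metallothionein genes had 8 higher and 1 not passing, MT1E at 2.37±0.15 (median 1.61, adjusted p = 9.77e-05). ATF4 genes had 12 higher, 2 lower and 5 not passing, DDIT4 at 2.92±0.11 (median 0.89, adjusted p = 0.00073). Replication genes had 2 higher, 24 lower and 5 not passing, RRM2 at -1.56±0.18 and E2F2 at -1.48±0.14 (median -0.54, adjusted p = 3.06e-05), while mitosis genes had 18 higher, 7 lower and 11 not passing, CENPA at 1.11±0.13 and CDK1 at 0.93±0.10 (median 0.23, adjusted p = 0.0957). Antigen presentation genes had 10 higher, 3 lower and 9 not passing, HLA-DPA1 at least 6.56-fold and HLA-DMB by 2.83±0.19 (median 0.29, adjusted p = 0.0218, adjusted p = 0.177 with an estimated correlation). Histone genes had 1 higher, 10 lower and 1 not passing, H4C8 at -2.16±0.16 (median -1.004, adjusted p = 0.000886, adjusted p = 0.067 with an estimated correlation). Germline genes had 16 higher, 8 lower and 23 not passing (16 and 9 adjusted over the list alone), CT45A1 at 2.10±0.14 and PAGE2 at least 2.55-fold, and their median of -0.04 differed in sign from the mean of 0.12 and the test (adjusted p = 0.52). SFRP1 rose by 4.32±0.15, MEG3 by 2.68±0.17, H19 by 2.52±0.14 and DNMT3B by 0.71±0.12.

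**Figure D2:**
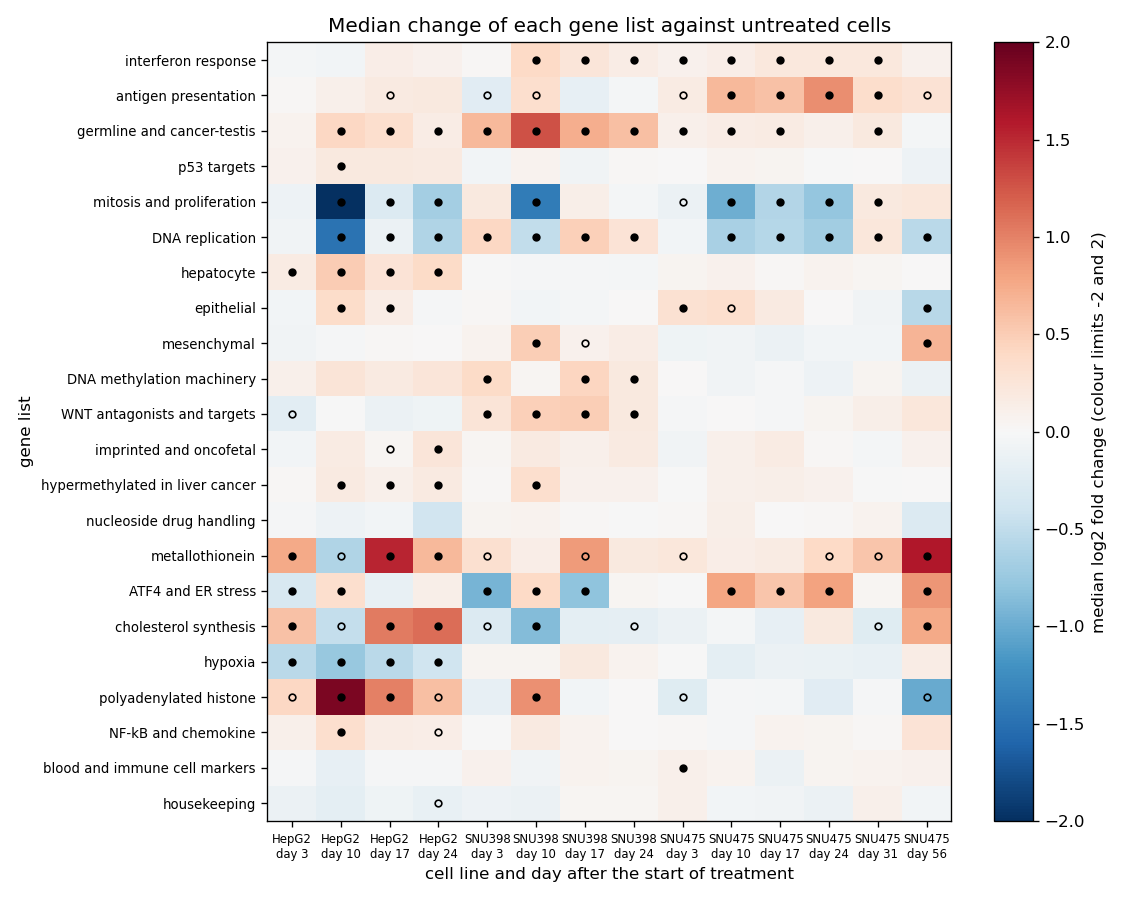
Median log2 fold change of each gene list against untreated cells, with a dot where the list test passed, filled where it also passed with an estimated correlation. The mitosis list had medians of -2.31 in HepG2, -1.41 in SNU398 and -0.98 in SNU475 at day 10.

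Genes raised in all 3 lines were counted on each shared day. At day 3 they numbered 27, with 4.63 expected if the lines were independent, and the genes with the largest smallest rise were H19 (at least 28.9-fold in HepG2, at least 2.29-fold in SNU398 and 4.01±0.14 in SNU475), S100A4 (1.56±0.17, 1.71±0.17 and 1.49±0.17), NNAT, LRCH4 (4.02±0.13, 3.27±0.13 and 1.07±0.13) and LXN. Lowered in all 3 were 23, with 2.66 expected (7 without SNU475 untreated replicate 1, 13 without its day 3 replicate 2 and 15 without HepG2 untreated replicate 1), among them STX8 (-0.93±0.15, -1.99±0.15 and -0.75±0.15), PRKCA (-0.98±0.13, -1.30±0.13 and -0.75±0.13), AGAP1 and FAF1. At day 10 the shared sets grew to 235 higher (64.2 expected) and 238 lower (31.1 expected). PAGE2B, PAGE2, PAGE5, TKTL1 (2.55±0.16, 3.64±0.16 and 3.12±0.16) and MAGEA8 led the increases, and the kinesin and chromosome genes KIFC1 (-1.70±0.13, -1.94±0.13 and -1.43±0.13), KIF20A (-2.57±0.12, -2.13±0.12 and -1.41±0.12), KIF11, CDCA3 and NCAPG the decreases. At day 17 there were 87 higher (34.8 expected), including GPNMB (1.83±0.18, at least 2.61-fold and 2.11±0.18) and MAGEA9B, and 24 lower (17 expected), including ADGRG6 (-0.89±0.15, -0.95±0.15 and -0.72±0.15), NEK2 and CHMP3. At day 24 there were 85 higher (41.8 expected), with PAGE2B, PAGE5, PAGE2, LOC105379362 (1.77±0.14, 1.63±0.14 and 2.67±0.14) and GPNMB, and 25 lower against 27.1 expected, with PANX2 (-0.98±0.14, -0.77±0.14 and -0.91±0.14), METRN and OSR1. Without SNU475 untreated replicate 1 the lowered sets of days 17 and 24 held 14 and 15 genes. On the deposited values 133 were raised and 427 lowered at day 10, and 89 and 43 lowered at days 17 and 24. As a pair, SNU398 and SNU475 shared more genes than independent lines would at day 3 (118 higher against 56.73) and day 10 (505 against 354.5). They shared fewer at day 17 (229 against 241.1, and 77 lower against 149.4) and day 24 (306 against 311.3, and 124 lower against 215.8). From day 10 on treated SNU398 shares an array set with untreated SNU475, so an offset of that set would move the 2 comparisons in opposite directions.

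**Figure D3:**
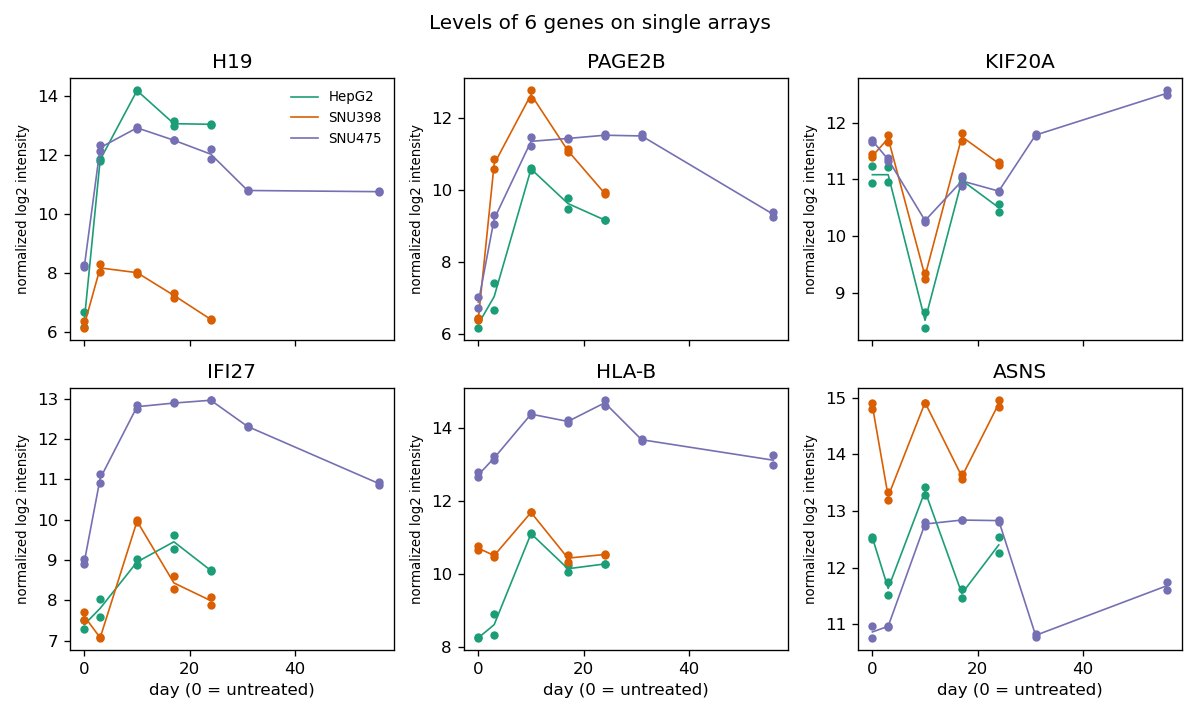
Levels of H19, PAGE2B, KIF20A, IFI27, HLA-B and ASNS on single arrays over the days, with lines through the means of 2 arrays. In HepG2 H19 stood at 6.42 untreated, 14.17 at day 10 and 13.03 at day 24.

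Lasting changes were sought by overlap between days of a line, each against the same 2 untreated arrays. In HepG2 831 of the 1248 genes higher at day 3 (66.6 percent) were higher at day 24, with 167.4 expected, and 572 of 1000 lower genes (57.2 percent), with 125.6 expected. SNU398 kept 1098 of 2606 higher (42.1 percent, 286.9 expected) and 1001 of 2525 lower (39.6 percent), and SNU475 258 of 333 higher (77.5 percent, 61.56 expected) and 129 of 247 lower (52.2 percent). From day 10 to day 24 SNU475 kept 1416 of 1775 higher genes (79.8 percent). With no effect simulated almost no gene passes, so its 0 genes in common are no baseline. Between changes at days 3 and 24 the simulated r across genes was 0.50 and the covariance 0.012. In HepG2, SNU398 and SNU475 r was 0.65, 0.71 and 0.40, below the simulated value in SNU475, and the covariance 0.104, 0.132 and 0.051. The 2 untreated arrays, which could not be split, may give part of the excess. So may an offset between array sets in SNU398, and in SNU475 from day 10 on.

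Direct comparison of days, across array sets in SNU475 alone, asked what moved after day 3. In HepG2 from day 3 to day 24, 1240 genes rose and 1207 fell. IGF2 rose by 1.55±0.18, HPX by 1.62±0.14 and HLA-B by 1.67±0.14, with FCER1G at -2.42±0.19. Mitosis genes had 30 lower and 6 not passing (0 and 35 adjusted over the list alone), CEP55 at -1.02±0.15 (median -0.58, adjusted p = 1.58e-20). In SNU398 1526 rose and 1239 fell (1496 in total without day 24 replicate 1), TRIB3 by 2.48±0.13 up, and NNAT and H19 fell, H19 at least 2.29-fold to background. ATF4 genes had 16 higher and 3 not passing (17 and 0 adjusted over the list alone), DDIT4 at 1.86±0.11 (median 0.89, adjusted p = 1.09e-20). In SNU475 2841 rose and 2280 fell to day 24, 55.5 percent rising against 39.5 with median scaling and 18.3 on the deposited values, and 3381 rose and 3908 fell to day 56, 46.4 percent against 23.6 on the deposited values. MEG3 rose by 3.09±0.17 and SFRP1 by 4.32±0.15 to day 56, and CLDN7 fell by 3.45±0.15. Mesenchymal genes from day 3 to day 56 had 21 higher, 4 lower and 5 not passing (22 and 5 adjusted over the list alone), CDH11 at least 13.2-fold (median 0.89, adjusted p = 6.62e-07, but median -0.28 and 0.716 above background on all 34 arrays), and epithelial genes 2 higher, 13 lower and 5 not passing, KRT8 at -2.95±0.15 (median -0.94, adjusted p = 4.86e-05).

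Differences between lines were tested as interactions on the mean of days 3, 10, 17 and 24 against untreated. MEG3 rose more in HepG2 than in SNU398 by 3.71±0.19 and GAGE12G by at least 9.52-fold, while CRIP1 rose at least 27.7-fold and CYBA at least 23.9-fold more in SNU398. H19 (adjusted p = 2.8e-20, above) and CTCFL (adjusted p = 1.1e-18, below) differed as well, with no size given, since both lines lay at background untreated. There were 2721 genes above and 2770 below, 49.6 percent above against 34.2 with median scaling. Between HepG2 and SNU475 the response was at least 27.8-fold higher for MEG3, 10.6-fold for TM4SF4 and 10.9-fold for WDR72, and lower for SLC2A3 (-3.84±0.15), TNNC1 (-3.49±0.22) and S100P (at least 7.93-fold), among 1944 above and 1948 below, 49.9 percent above against 62.9 with median scaling and 80.5 on the deposited values. Between SNU398 and SNU475 it was at least 27.7-fold higher for LDHB and 22.7-fold for CYBA, higher for CTCFL (adjusted p = 4.8e-19) and lower for H19 (adjusted p = 1.5e-14), both at background in untreated SNU398, and lower for HCP5 (-3.23±0.15) and TRIB3 (-2.79±0.14), among 2808 above and 2715 below, 50.8 percent above against 72.7 with median scaling and 77.5 on the deposited values.

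Gene groups differed between lines too. The germline list of HepG2 lay below that of SNU398, 2 above, 22 below and 23 not passing (2 and 24 adjusted over the list alone), GTSF1 at least 5.83-fold below (median -0.47, adjusted p = 8.55e-08, 0.459 above background on all 34 arrays), and that of SNU398 above that of SNU475, 26 above, 5 below and 16 not passing (28 and 5 adjusted over the list alone), GTSF1 at least 8.04-fold above (median 0.54, adjusted p = 1.23e-07, 0.0601 above background on all 34 arrays). Cholesterol synthesis changed more upward in HepG2 than in SNU398, 13 above and 3 not passing (14 and 0 adjusted over the list alone), HMGCS1 at 1.90±0.14 (median 0.79, adjusted p = 3.89e-09), and than in SNU475, 12 above and 4 not passing (14 and 0 adjusted over the list alone), LSS at 1.14±0.15 (median 0.60, adjusted p = 7.19e-07). Hypoxia genes of HepG2 lay below those of SNU398 in 13 cases with 8 not passing, HK2 at -2.25±0.16 (median -0.44, adjusted p = 1.81e-05). Antigen presentation genes of SNU398 lay below those of SNU475 in 15 cases with 7 not passing, HLA-B at -1.30±0.15 (median -0.52, adjusted p = 4.12e-05), and so did ATF4 genes, 3 above, 15 below and 1 not passing, ASNS at -2.18±0.13 (median -0.78, adjusted p = 1.1e-06).

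Lists whose members are silent in some group depend on the background filter. When genes had to be above background on all 34 arrays, 8588 genes stayed, and each germline call against untreated cells in the 3 lines was lost. Germline medians turned to -0.59, -0.01 and -0.37 at days 10, 17 and 24 in HepG2, to -0.02 at day 10 in SNU398, and in SNU475 to -0.36 at day 10, -0.28 at day 17 and -0.86 at day 24 (adjusted p = 0.015). In SNU398 the germline list stood at adjusted p = 0.0581, 0.0679 and 0.237 at days 3, 17 and 24, and in SNU475 at 0.342 and 0.322 at days 3 and 31. Members such as PAGE2 and PAGE5, at background in untreated HepG2, were removed by construction.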

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

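Tests chosen only after the result was seen are those of separate normalization, of HepG2 admixture, of a single share of HepG2 or of SNU398 cells at day 56, of an offset between array sets in genes silent in the untreated arrays of the first set, and of a shared deviation of the untreated HepG2 arrays, as is the requirement that the share of 175 SNU475 genes pass its bound by more than the binomial spread.

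SNU475 at day 56 stood far from untreated cells, with 7298 genes called, SFRP1 up by 4.32 and TM4SF4 down at least 32.4-fold. Admixed SNU398 cells had a test fixed beforehand that was met: 72.7 percent of 11 genes abundant in SNU398 and silent in SNU475 to day 31 were higher at day 56 than at day 10 (median 1.34), CCND2 reaching 10.77, A2M 10.14 and HEY2 9.76. A later test took a share, 11.6 percent, from the rising genes alone, which partly fixes its count, so it decides nothing. Of the 11, 6 lay over 1 log2 unit below its level, GCG at 6.29 among them. Separate normalization as the whole cause is argued against, since day 56 differed from day 10 of its set in 6975 genes. The test of 1 HepG2 share, 1.45 percent and again from rising genes, decides as little, with 19 of 44 genes over 1 unit below. The 20.5 percent that were higher (median 0.07), about the share among all genes, lay between the bounds set and decide nothing. Replacement by another cell type cannot be told apart from a change within the cells. Of 175 genes at least 3 log2 units above the other lines in untreated SNU475, 46.3 percent were lower than at day 10 (median -0.23). This met the bound written beforehand, under 50 percent and above -0.5, by less than its spread. Late effects of SGI-110 and culture drift may contribute, untested without untreated arrays at day 56.

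In SNU398, 2606 genes were higher at day 3, and treated and untreated arrays lie in different sets. For 229 of them, silent in untreated HepG2 and SNU398 in the first set, untreated SNU475 in the second set lay a median of 0.21 above untreated HepG2, against a change of 0.67 in SNU398, which lies between the bounds set for an offset of probes. For the other 2377 genes no value decides. A test written beforehand, on genes silent in both sets, was set aside because that selection bounds its outcome. A response to SGI-110 and an offset between sets cannot be told apart in either part, because no group was measured in both sets.

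Hypoxia genes were lower than in untreated HepG2 on every treated day, which could come from the 2 untreated arrays. Of 21 measured, 11 differed between day 3 and day 10 and 5 between day 3 and day 24, but days may differ on top of a deviation that they share. A response to SGI-110, the state of the untreated cultures and medium or density at harvest cannot be told apart, since HepG2 has no other untreated arrays.

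Direct tests between days 3 and 24 called 2447 genes in HepG2 and 2765 in SNU398. Across sets SNU475 had 5121, and 7289 from day 3 to day 56 (1742 from day 10 to day 24, within a set). Responses, all measured across sets, differed in 5491 genes between HepG2 and SNU398, 3892 between HepG2 and SNU475 and 5523 between SNU398 and SNU475.

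Genes ranked first are given by size where all groups were above background, else by a bound on the log2 difference or adjusted p alone. Between HepG2 and SNU398 these were MEG3 (3.71), GAGE12G (bound 3.25), H19 (adjusted p = 2.8e-20), CRIP1 (bound -4.79), CYBA (bound -4.58) and CTCFL (adjusted p = 1.1e-18). Between HepG2 and SNU475 they were MEG3 (bound 4.80), TM4SF4 (bound 3.41), WDR72 (bound 3.44), SLC2A3 (-3.84), TNNC1 (-3.49) and S100P (bound -2.99), and between SNU398 and SNU475 LDHB (bound 4.79), CYBA (bound 4.50), CTCFL (adjusted p = 4.8e-19), HCP5 (-3.23), TRIB3 (-2.79) and H19 (adjusted p = 1.5e-14).

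Lists whose test differed between days are given by their medians. From day 3 to day 24 in HepG2 these were antigen presentation (0.10, adjusted p = 0.217 with an estimated correlation), germline (0.11), mitosis (-0.58), replication (-0.47), hepatocyte (0.34), imprinted (0.26), hypermethylated (0.09), ATF4 (0.48) and cholesterol genes (0.61). In SNU398 they were interferon (0.18), mitosis (-0.18, adjusted p = 0.0728 with an estimated correlation), hypermethylated (0.07) and ATF4 genes (0.89), and in SNU475 antigen presentation (0.67), mitosis (-0.62), replication (-0.69) and ATF4 genes (0.74). From day 3 to day 56 SNU475 had replication (-0.48), epithelial (-0.94), mesenchymal (0.89), ATF4 (0.72) and cholesterol genes (0.93). With an estimated correlation its calls for mitosis (0.24, adjusted p = 0.102), WNT (0.37, 0.0834), metallothionein (0.67, 0.0866) and histone genes (-0.57, 0.202) were lost.

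Between HepG2 and SNU398 the lists that differed were germline (-0.47), mitosis (-0.53), replication (-0.77), hepatocyte (0.47), WNT (-0.46), ATF4 (0.35), cholesterol (0.79) and hypoxia genes (-0.44), with mesenchymal (-0.27, adjusted p = 0.0601) and histone genes (0.65, 0.059) lost with an estimated correlation. Between HepG2 and SNU475 they were hepatocyte (0.29), ATF4 (-0.43), cholesterol (0.60), hypoxia (-0.45) and histone genes (1.19), with antigen presentation (-0.36, adjusted p = 0.0834) and mitosis (-0.22, 0.0629) lost with an estimated correlation. Between SNU398 and SNU475 they were antigen presentation (-0.52), germline (0.54), replication (0.70), WNT (0.38) and ATF4 genes (-0.78), with mitosis (0.31, adjusted p = 0.0897) and cholesterol genes (-0.29, 0.19) lost with an estimated correlation. Left-out arrays ended the calls from day 3 to day 24 in HepG2 of antigen presentation (0.124 without day 3 replicate 2 and 0.0932 without day 24 replicate 2), imprinted (0.0714 without day 3 replicate 1) and hypermethylated genes (0.0689 without day 3 replicate 1 and 0.0676 without day 24 replicate 1). They also ended those of histone genes in SNU475 from day 3 to day 56 (0.0651 without day 3 replicate 1) and of cholesterol genes between SNU398 and SNU475 (0.0519 without SNU398 untreated replicate 1 and 0.0721 without SNU475 untreated replicate 2). Requiring signal above background on all 34 arrays ended the calls from day 3 to day 24 of germline (0.347), hepatocyte (0.99), imprinted (0.223) and hypermethylated genes (0.0797) in HepG2 and of hypermethylated genes in SNU398 (0.0839). From day 3 to day 56 it ended those of mesenchymal (0.716) and WNT genes (0.514) in SNU475. Between HepG2 and SNU398 it ended germline (0.459), hepatocyte (0.433) and mesenchymal genes (0.842), between HepG2 and SNU475 antigen presentation (0.0954) and hepatocyte genes (0.254), and between SNU398 and SNU475 germline genes (0.0601).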

How the results depend on the processing

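References within an array set and HepG2 against SNU475 at day 3 alone were chosen once the sets were seen, the other alternatives at the start. The values below concern 29 counts of genes, 462 list results and the named genes, each recomputed with 1 choice changed.

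Every count, higher and lower genes together, stayed within 1.5 times its value under median scaling and without background correction or a filter. So it did with the mean of a gene's probes, a trended robust prior and the compared lines alone. With median scaling SNU398 at day 24 had 2956 higher and 802 lower, against 1684 and 1361. The filter for genes above background on all 34 arrays tested 8588 genes, fewer by construction, and called 367 genes in SNU475 at day 3, and raised in all 3 lines were 14 genes at day 3, 42 at day 17 and 55 at day 24. On the deposited values, which keep the offsets between array sets, SNU475 had 6307 genes called at day 10, 5833 at day 17 and 5930 at day 31, and 133 genes were raised and 427 lowered in all 3 lines at day 10, 89 lowered at day 17 and 43 lowered at day 24. The median difference of all genes between SNU398 and SNU475 was 0.16 with median scaling and 0.18 as deposited, and between HepG2 and SNU475 0.16 as deposited, against 0.01 and -0.01. With median scaling SNU398 had a median of 0.12 at day 10 and 0.11 at day 17, against 0.03 and 0.02. Against day 10, in the same array set, SNU475 had 1742 genes called at day 24 and 4091 at day 31, a different contrast from that with untreated cells. The response of HepG2 and SNU475 at day 3 alone differed in 1485 genes, over 1 day instead of the mean of days. What lies behind the other differences in counts was not tested.

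Leaving out 1 array leaves a group of 1, which is assumed to vary like the other groups. Why these counts move was not tested. HepG2 at day 3 ranged from 1480 to 1842 genes, with 1480 and 1498 without untreated replicates 1 and 2 and 1485 without day 3 replicate 1. SNU398 at day 24 ranged from 1797 to 2035, with 1797 without untreated replicate 2 and 1906 and 1930 without day 24 replicates 1 and 2. SNU475 at day 3 ranged from 311 without untreated replicate 1 to 361 without untreated replicate 2, with 360 and 356 without day 3 replicates 1 and 2. For SNU475 at day 10 the range was 2006, without untreated replicate 1, to 2246. At day 17 it was 1318 and 1444 without untreated replicates 1 and 2 and 1342 and 1378 without day 17 replicates 1 and 2, and at day 31 it was 1242, 1421, 1360 and 1410 in that order. From day 3 to day 24 HepG2 ranged from 1523 to 1821, with 1523 and 1537 without day 24 replicates 1 and 2, and SNU398 from 1496 to 2352, with 1496 and 1753 without day 24 replicates 1 and 2 and 1651 without day 3 replicate 1. Genes lowered in all 3 lines ranged from 7 to 25 at day 3 (7 without SNU475 untreated replicate 1, 13 without its day 3 replicate 2, 15 without HepG2 untreated replicate 1), from 14 to 19 at day 17 (14 without SNU475 untreated replicate 1 or day 17 replicate 2, 15 without HepG2 untreated replicate 1 or day 17 replicate 2) and from 15 to 20 at day 24 (15 without SNU475 untreated replicate 1, 16 without HepG2 day 24 replicate 1).

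Among lists, the filter for all 34 arrays had the widest effect, 359 results the same, 34 losing their call, 14 gaining one and 13 turning. Germline medians became -0.59, -0.007 and -0.37 in HepG2 at days 10, 17 and 24, -0.018 in SNU398 at day 10, -0.36, -0.28 and -0.86 in SNU475 at days 10, 17 and 24, and -0.20 in HepG2 and -0.75 in SNU475 from day 3 to day 24. The imprinted list of HepG2 turned to -0.011 at day 17, and the mesenchymal list to -0.16 in SNU475 at day 56, -0.28 from day 3 to day 56 and 0.089 between HepG2 and SNU398. In HepG2 it also ended the hypermethylated (0.243) and hepatocyte calls (0.597) at day 17, and in SNU398 the mesenchymal call at day 17 (0.266). The other calls that it ended are given beside each list.

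Under the other settings few lists lost a call. Median scaling and deposited values ended the interferon call of SNU398 at day 17 and the cholesterol difference between SNU398 and SNU475 (adjusted p = 0.0943 and 0.102). Deposited values also ended cholesterol in SNU398 at day 24 and mitosis in SNU475 from day 3 to day 56 (both 0.0598). With the compared lines alone the imprinted and hypermethylated calls of HepG2 at day 17 (0.108 and 0.08) and the antigen presentation call of HepG2 from day 3 to day 24 (0.0601) were lost. Leaving out 1 array ended 38 list calls and turned 2 medians, that of the imprinted list in HepG2 at day 3 (-0.110 to 0.056, the highest without untreated replicate 1) and between HepG2 and SNU475 (-0.046 to 0.046, the highest without SNU475 untreated replicate 1). Among those ended were WNT genes in HepG2 at day 3, antigen presentation in HepG2 at day 17 and cholesterol in SNU398 at day 24. With an estimated correlation these calls were lost too (adjusted p = 0.11, 0.193 and 0.182). So were those of imprinted genes in HepG2 (0.0537) and mesenchymal genes in SNU398 (0.0679) at day 17.

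Replicate numbers do not pair the samples. Deviations of arrays with the same number correlated from -0.10 to 0.17 over 10 pairs of groups in HepG2, -0.14 to 0.06 over 10 in SNU398 and -0.04 to 0.08 over 21 in SNU475, with medians of -0.01, 0.00 and 0.00. With the replicate block all 29 counts stayed within 1.5 times, as in HepG2 at day 3 (2186) and SNU475 at day 3 (570). Of lists, 1 call was lost, that of imprinted genes in HepG2 at day 17 (adjusted p = 0.0532), and 2 were gained, and 8 named genes lost their call.

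Of the named genes, CD3D in HepG2 at day 24 turned to 0.13 without a filter, where a brighter probe represents it, and with the mean of probes UBE2C in SNU398 at day 24 turned to 0.034 and DNMT3A between HepG2 and SNU475 to -0.017. By the rule above, no named gene turned under the other settings or without any single array. Genes called in neither fit may have changed sign. Leaving out an array ended a call in 592 cases, the mean of probes 56, the compared lines alone 34, no filter 29, median scaling 26 and deposited values 25. Signal over background limits genes such as AFP in SNU398, for which a fold change is a bound.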
